A study of Mus musculus with 30 samples.

How the data were processed

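Expression was measured on 30 single-colour Illumina mouse bead arrays. The RNA came from primary mouse embryonic fibroblasts (MEFs), from MEFs transformed by p53 knockdown and overexpressed HRasV12, and from tumours that the transformed MEFs formed in nude mice. Each cell type was either wildtype (FVB/N) or null for Smchd1 through the MommeD1 point mutation on that background. Per the labels' protocols, primary MEFs were passaged 2 to 3 times and transformed MEFs were harvested 2 weeks after transformation. There were 3 arrays per genotype in each culture stage and 9 per genotype in tumours, where 3 recipient mice per genotype each had 3 arrays.

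The deposited values are log2 intensities, and the submitters' processing notes name BeadStudio, R 2.15.1 and limma 3.12.1. The sorted values of the arrays differed by at most 0.0291 within a stage and by up to 0.256 (transformed) and 0.4898 (tumours) from primary MEFs, so it appears that the authors' quantile normalization had been applied to each stage separately. The median deposited log2 value was 6.07 in primary MEFs, 6.06 in transformed MEFs and 6.25 in tumours. The background correction behind them is not given in the sources used here. Scanner tables with intensities and detection p-values were also deposited by the authors, but their column names match no sample label, so their 480 columns of array values were assigned to no sample. The plan had been to start from those intensities, and the deposited log2 values were used in their place. From the scanner tables only the probe names and the number of arrays on which a probe was detected were taken, after all 45281 rows of both scanner tables had been matched.

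All 30 arrays were quantile normalized together. Probes with a detection p under 0.01 on at least 3 arrays were kept (20254 probes), and each gene was represented by its kept probe with the highest mean, which left 13870 genes. Gene names are those of the files, updated through a table of the GRCm38.p6 assembly that was used for names and chromosomes only. Of the probes, 27400 carried a current symbol, 8341 an older one, 191 a symbol shared by several genes, and 9349 had no match and kept the name in the file. Probes can cross-hybridize within gene families such as the protocadherins, Mup, Lce and Klra genes and Pisd pseudogenes, so single members of these are uncertain. The number of arrays limits the precision, and background was taken per group as the 95th percentile of probes detected on no array.

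A tumour replicate was a recipient mouse, the mean of its 3 arrays, so every group had n = 3. Arrays of one recipient deviated together from their group mean (mean correlation 0.38 in wildtype and 0.33 in null), unlike arrays with the same replicate number (-0.26 and -0.15). The labels do not say whether culture replicates are separate cultures or embryos, so p-values measure the spread between these samples, which may be technical. One limma fit (version 3.58.1, R 4.3.3) of all 6 groups with a shared estimate of the spread gave the genotype difference in each stage, the differences between those differences, and the stage differences in wildtype. It had 12 residual degrees of freedom. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, over 26 lists with at least 3 measured genes and 3 genotype comparisons (78 tests). The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest rises and 12 largest falls among called genes whose replicates do not overlap, up to 4 members per list, up to 6 genes per direction for the other comparisons, and Smchd1, Trp53, Hras, Xist and the Y-linked genes.

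The fits were tested on simulated data only after they had been run on the deposited values, and the shared spread did not pass this test for tumours. The spread was simulated in 3 ways and 4 fits were run on each. In 5 simulations per comparison, 200 of 13870 genes were changed, and each stage kept its own measured spread. False genes then made up 8.9% of calls in primary MEFs, 5.3% in transformed MEFs and 76.4% in tumours. These shares depend on the 200 changed genes and are not estimates for the real lists. In primary MEFs the shared fit made 5 to 18 false calls per simulated run. With each stage's spread shrunken towards a common value it made 3 to 9. Under the unshrunken spread the 5 runs also gave 636 true calls. These counts of false calls therefore do not carry over to the 15 genes called on the real values. The same fit gave 4.5%, 4.6% and 3.8% when the simulated spread was equal in all stages, so the failure comes from the unequal spread. The median variance between replicates was 0.0947 in tumours, 0.0196 in primary MEFs and 0.0166 in transformed MEFs. A separate fit for each stage, listed beforehand as an alternative, gave false shares of 5%, 4.1% and 4.2% under the stages' own spread. It recovered 83.7%, 85.9% and 18.6% of genes changed by 1 log2 unit in primary MEFs, transformed MEFs and tumours, against 76.8%, 74.5% and 79.7% with the shared spread. A fit with one weight per stage, added after this failure, did not repair it (34.9% false in tumours). A fit of the 4 culture groups alone, added too, gave 19.1% in primary and 12.5% in transformed MEFs, and 6.9% to 7.3% for the difference between them, where the shared fit gave 3.2% to 3.3%. For the difference between tumours and transformed MEFs, 40.2% of simulated calls were false with the shared spread and 29.6% with stage weights, and no fit made here held that rate. The shared fit stays the main one because it was fixed beforehand, and counts of the separate fit are given beside its counts.

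Each genotype comparison lies within the same chips, as each chip carried both genotypes. Primary MEFs were on 1 chip, transformed MEFs on another and tumours on 3, so stage and chip cannot be told apart. Alternatives covered the normalization, the probe filter, the choice of probe, array weights, a replicate block, the tumour replicate, single chips, the sex chromosomes and leaving out each replicate.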

Results

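The 30 arrays fell into 6 groups, wildtype and Smchd1 null in each of 3 stages, with 3 replicates per group. Smchd1 encodes a non-canonical SMC protein that takes part in X inactivation and in the silencing of clustered autosomal genes. Smchd1 itself was lower in null samples at every stage by the probe that represents it. The log2 difference was -2.32 ± 0.12 (SE, n = 3) in primary MEFs, -2.13 ± 0.12 in transformed MEFs and -1.18 ± 0.12 in tumours. In the separate fit of tumours the last value had an SE of 0.15 and was not called by limma (adjusted p = 1). A second Smchd1 probe, detected on 15 arrays, was not above background in the null cultures. It was at least 1.37-fold lower there than in wildtype in primary MEFs and at least 1.4-fold lower in transformed MEFs, and differed by -0.66 ± 0.12 in tumours, and the others were detected on at most 2 arrays. Trp53 was at a log2 level of 10.97 in wildtype primary MEFs and fell by 3.38 ± 0.18 with transformation, while the representative Hras probe differed by -0.06 ± 0.11. Xist was detected on none of the arrays. Ddx3y, on the Y chromosome, was detected on all 30 by the probe that represents it.

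**Figure D1:**
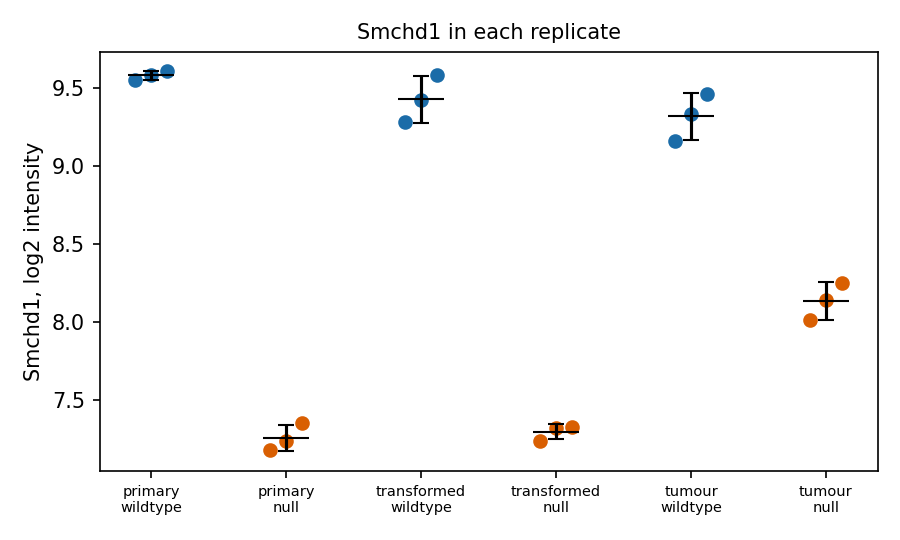
Log2 intensity of the representative Smchd1 probe in each of the 6 groups, with a point per replicate (recipient mouse in tumours) and the mean with its SD. Null tumours lay between 8.01 and 8.25, above null transformed MEFs at 7.24 to 7.33 and below wildtype tumours at 9.16 to 9.46.

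In primary MEFs, the comparison asks what loss of Smchd1 changes before transformation. The pseudogene Pisd-ps3 was 5.23-fold higher in null cells (log2 2.39 ± 0.18, n = 3), and Mkrn3, an imprinted gene of the Prader-Willi region, was 2.22-fold higher (1.15 ± 0.17). LOC236604 (1.35 ± 0.14), the clustered protocadherin Pcdhb3 (0.94 ± 0.14), the major urinary protein genes Mup2 (0.89 ± 0.1) and Mup1 (0.67 ± 0.12) and the immediate early gene Fosb (1.42 ± 0.24) were also called higher. Lce1a2, a late cornified envelope gene of the epidermis, differed by 1.75 ± 0.28. These SEs rest on the spread shared over all stages and can understate that of primary MEFs. The replicate SD of Lce1a2 was 0.51 in null and 0.77 in wildtype primary MEFs, and that of Akr1cl 0.43 and 0.07. Besides Smchd1, the lysozyme gene Lyz1 (-0.86 ± 0.16), Akr1cl (-0.99 ± 0.15) and the carbonic anhydrase gene Car3 (-0.76 ± 0.13) were called lower. In all, limma called 15 of 13870 genes, 11 higher and 4 lower. The replicates of 10.3% of all genes did not overlap, where chance gives 10%. The separate fit called 7 genes, 5 of them among the 15. They were Smchd1, Pisd-ps3, Mkrn3, LOC236604 and Mup2, with Fos (1.01 ± 0.09) and Pcdhb22 (1.23 ± 0.12) besides, Fos being named after its values were seen, and it did not call Fosb, Lce1a2, Pcdhb3, Mup1, Lyz1, Akr1cl and Car3. The count of 15 became 39 without wildtype replicate 2 and 9 without null replicate 3.

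All 15 measured keratinocyte and epithelial markers had a positive difference in null primary MEFs. None was called over all genes and 2 were called higher adjusted over the list alone, Krt5 (1.09 ± 0.3) and Trp63 (0.69 ± 0.22). The median log2 difference was 0.73 (camera adjusted p = 2.17e-15). With an estimated correlation the adjusted p was 0.0362, but it was 0.37 in the separate fit. The mean of the 15 markers was 8.55, 9.34 and 8.87 in the wildtype replicates and 9.45, 9.4 and 10.03 in the null ones, and the 14 measured Lce genes, which are not in this list, all had a positive difference. In the same comparison all 17 skeletal muscle markers had a negative difference with none called (median -0.27, camera adjusted p = 0.00172, adjusted p = 0.622 with an estimated correlation). So did 13 of 17 macrophage markers with none called (median -0.08, camera adjusted p = 0.0493, adjusted p = 0.761 with an estimated correlation). Neural markers had a negative difference in 9 of 10 members with none called (median -0.14, adjusted p = 0.158 with an estimated correlation). Fry gave them an adjusted p of 0.00604, but 0.153 in the separate fit. For 4 genes of the Snrpn and Igf2r imprinted clusters, with 1 called higher, fry gave 0.16, and 0.00744 in the separate fit. Of the 16 measured clustered protocadherins, 1 was called higher, and 6 were higher adjusted over the list alone (camera adjusted p = 1.5e-09, adjusted p = 0.0639 with an estimated correlation). Interferon response genes had a positive difference in 25 of 26 members with none called (camera adjusted p = 4.65e-12, adjusted p = 0.101 with an estimated correlation).

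In transformed MEFs, the same question is asked after p53 knockdown and HRasV12. Of 26 measured interferon response genes 16 were called lower in null cells, none higher and 10 were not called, and 22 were lower adjusted over the list alone. Gbp3 (-1.44 ± 0.12), Ifit3 (-1.64 ± 0.22), Igtp (-1.24 ± 0.18) and Rtp4, all interferon-induced genes, had the smallest p among the members of this list. Rtp4 was below background in null cells and at least 1.71-fold lower. The list median was -0.89 (camera adjusted p = 7.69e-41, adjusted p = 0.0063 with an estimated correlation). In the separate fit the adjusted p with an estimated correlation was 0.167, and fry gave 0.00179. All 28 measured cell cycle genes had a positive difference, with a median of 0.51 (camera adjusted p = 2.55e-21, adjusted p = 0.0396 with an estimated correlation). Among them only the mitotic checkpoint gene Bub1b (0.62 ± 0.13) was called over all genes, and 23 were called adjusted over the list alone. In the separate fit the estimated correlation gave this list an adjusted p of 0.0639. Fry gave it 0.0037, and 0.0015 in the separate fit.

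Genes higher in null transformed MEFs included Klra4 (2.73 ± 0.35) and Klra16 (2.09 ± 0.35), which encode Ly49 receptors of natural killer cells. Others were Pisd-ps3 (1.28 ± 0.18), Pcdhb22 (1.31 ± 0.24), Spin2c (1.49 ± 0.13) and Elavl2 (1.47 ± 0.21), which encodes a neuronal RNA-binding protein. LOC100040020 (3.04 ± 0.48), LOC100038894 (2.57 ± 0.41) and Csf2ra (1.5 ± 0.2) were higher too. LOC673578 was below background in wildtype and at least 3.1-fold higher in null cells, measured against the background percentile, and Sult4a1 at least 2.06-fold. Of 4 measured genes of the Snrpn and Igf2r imprinted clusters, Mkrn3 (1.01 ± 0.17) and Snurf (0.88 ± 0.18) were called higher, while Ndn (1.23 ± 0.31) and Igf2r (-0.45 ± 0.33) were not called (camera adjusted p = 0.000216, adjusted p = 0.0396 with an estimated correlation and 0.385 in the separate fit). Fry gave this list an adjusted p of 0.00449, and 0.0363 in the separate fit. Besides interferon genes, Rtl3 (-1.87 ± 0.18), Angptl1 (-1.83 ± 0.32), Cyp2f2 (-1.79 ± 0.28), the alcohol dehydrogenase gene Adh1 (-1.56 ± 0.15), the complement gene C2 (-1.55 ± 0.31) and Podn (-1.55 ± 0.2) were lower. In all, limma called 147 genes, 44 higher and 103 lower. The replicates of 28.36% of all genes did not overlap, where chance gives 10%. The separate fit called 906 genes, 413 higher and 493 lower, with 144 of the 147 among them. Without any one transformed replicate the shared fit called between 45 and 97 genes.

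**Figure D2:**
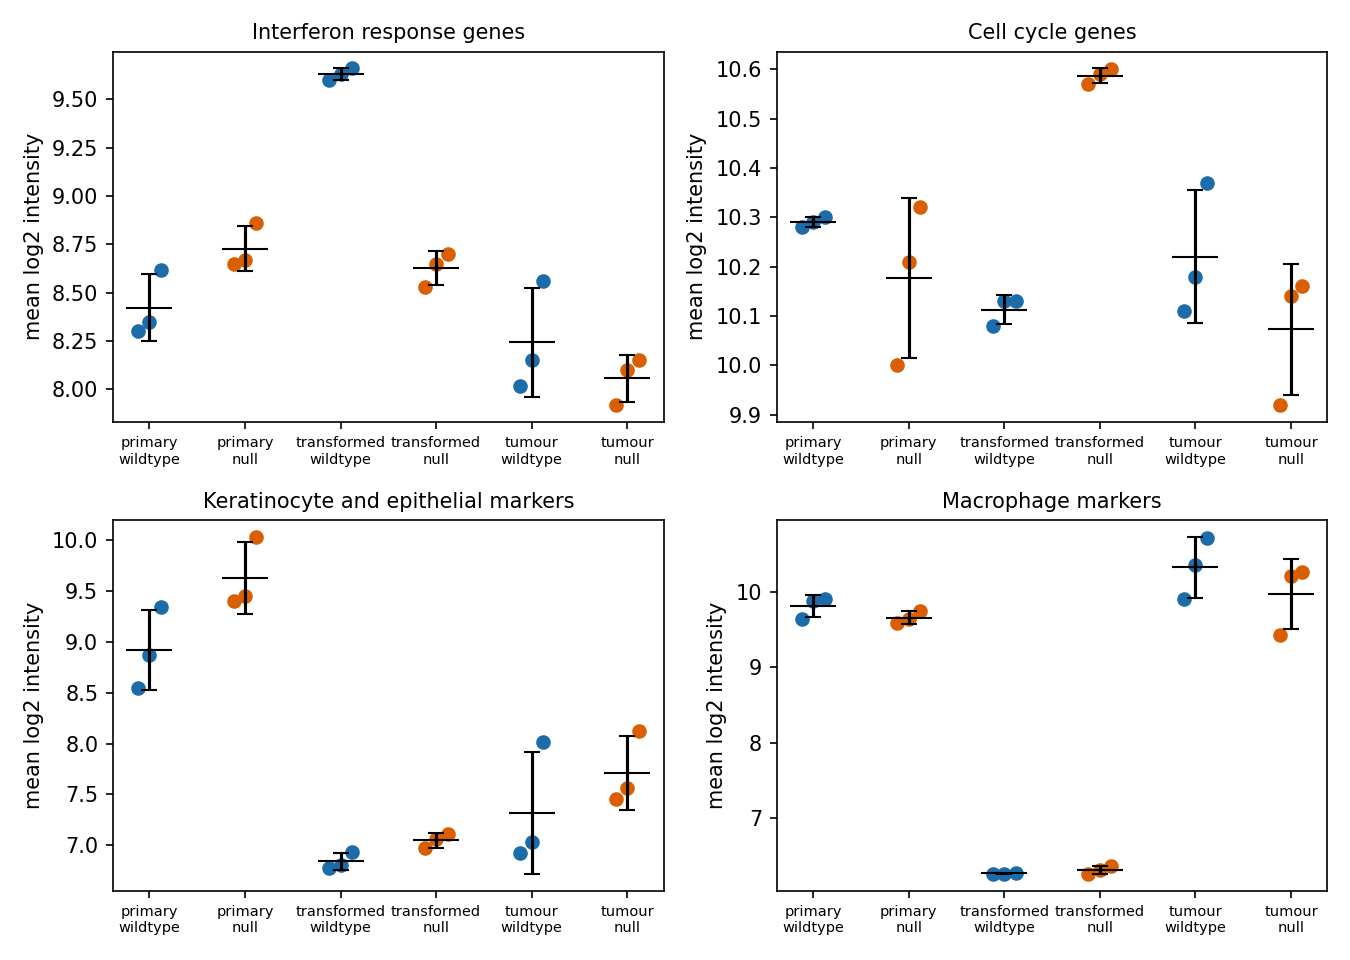
Mean log2 intensity of the measured members of 4 gene lists in each replicate, with a point per replicate and the group mean with its SD; vertical axes differ and do not start at 0. Interferon response genes lay at 9.6 to 9.66 in wildtype and 8.53 to 8.7 in null transformed MEFs.

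In tumours, no gene was called by the fit that kept its error rate on simulated data, so the following are values and not changes. In that fit some lists passed camera at the preset correlation, such as skeletal muscle markers (adjusted p = 5.79e-06). None passed with an estimated correlation or with fry. Pcdhb22 differed by 2.35 ± 0.34 (SE of the separate fit, n = 3 recipient mice), the imprinted gene Ndn by 2.25 ± 0.48, Mkrn3 by 1.35 ± 0.23 and Pisd-ps3 by 1.65 ± 0.27. Gad1, the glutamate decarboxylase of neurons, differed by 2.79 ± 0.62, the transcription factor gene Onecut2 by 2.57 ± 0.38, Pcdh17 by 1.87 ± 0.4 and Phf21b by 1.28 ± 0.23. The shared fit called 19 genes, 18 higher and Smchd1 lower, and the separate fit called 0, with 313 genes at an unadjusted p under 0.05. Among 13870 genes those 313 are a smaller share than the 0.05 that chance gives. The replicates of 6.68% of all genes did not overlap, fewer than the 10% that chance gives. Of the 9 other splits of the 6 recipients, 8 gave more called genes than the genotypes did, up to 927. Without wildtype recipient 3 the shared fit called 690 genes. Each tumour chip alone, where an array stands for a mouse, gave 147, 694 and 1164 genes in the shared fit. Skeletal muscle markers had a median difference of 1.08 (0.85 with group means held at background) with none of 17 members called and 7 higher adjusted over the list alone (camera adjusted p = 3.06e-07, adjusted p = 0.302 with an estimated correlation). Their mean was 9.11 in 1 null recipient and between 7.05 and 7.99 in the other recipients. All 17 macrophage markers had a negative difference, with a median of -0.37 (camera adjusted p = 0.000636, adjusted p = 0.472 with an estimated correlation). Of 4 measured genes of the Snrpn and Igf2r imprinted clusters, 2 were called higher by the shared fit (list median 0.71). Camera with an estimated correlation gave this list an adjusted p of 0.0423 and fry 0.00279, against 0.37 and 0.134 in the separate fit.

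**Figure D3:**
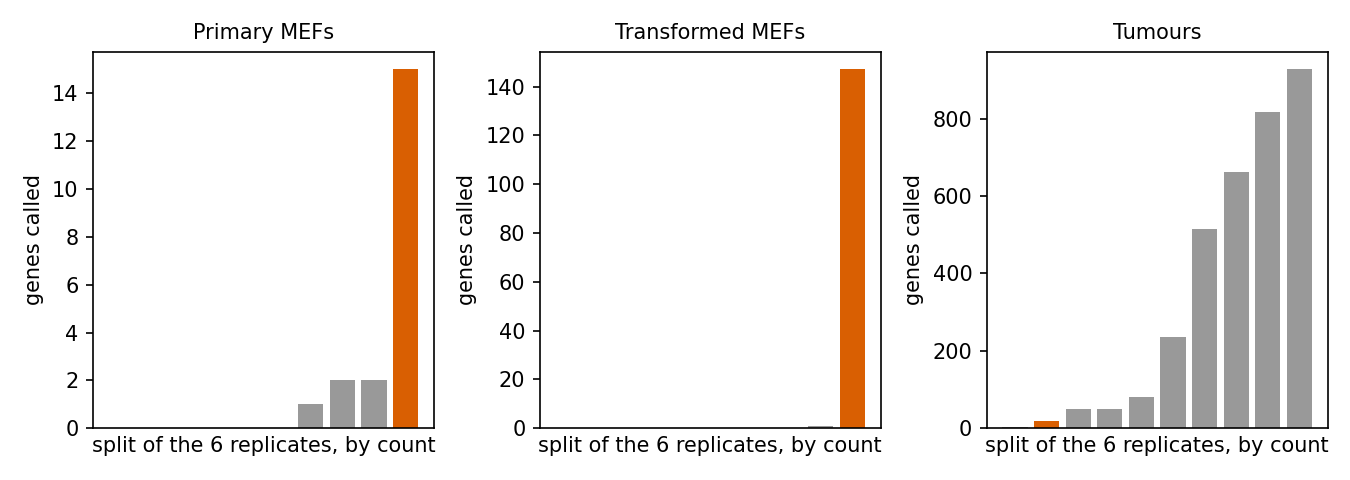
Number of genes called by the shared fit for each of the 10 ways to split the 6 replicates of a stage into 3 against 3, ordered by count, with the split by genotype in orange and the others in grey. The split by genotype gave 15 genes in primary MEFs and 147 in transformed MEFs, above the other splits, and 19 in tumours, where other splits reached 927.

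The genotype difference itself differed between transformed and primary MEFs for 30 genes, 3 upward and 27 downward by limma. Klra4 (2.62 ± 0.5), Elavl2 (1.55 ± 0.29) and Spin2c (1.51 ± 0.19) shifted upward, with Klra4 not above background in primary MEFs of either genotype. Fosb (-2.46 ± 0.33), Cyp2f2 (-2.25 ± 0.4), the acute phase gene Saa3 (-2.01 ± 0.39), Gm4951 (-2.01 ± 0.21) and Ifit3 (-1.87 ± 0.31) shifted downward, with Gm4951 below background in null transformed MEFs. In list tests chosen after the genotype results were seen, interferon response genes shifted by a median of -1.26 (camera adjusted p = 1.28e-48, adjusted p = 0.0019 with an estimated correlation). Cell cycle genes shifted by 0.64 (camera adjusted p = 1.06e-21, adjusted p = 0.0396 with an estimated correlation). A fit of the 4 culture groups alone, added after the data were seen, called 327 genes with all 30 among them, at a simulated false share of up to 7.3%. Between tumours and transformed MEFs the shared fit called 8 genes, with Rtl3 at 1.88 ± 0.25, Adh1 at 1.61 ± 0.22 and the replication gene Cdc45 at -0.94 ± 0.15. Rtl3 and Adh1 were not above background in tumours of either genotype. The fit with stage weights called 0 of these, with 800 of 13870 genes at an unadjusted p under 0.05, near the share that chance gives. In the same later list tests, interferon response genes had a median of 0.85 for this difference and cell cycle genes -0.7. Both passed camera with an estimated correlation (adjusted p = 0.0396), but no fit held its simulated error rate here. Within tumours the genotype difference had a median of -0.18 for interferon and -0.16 for cell cycle genes, with none called in either list. Mkrn3, Pisd-ps3 and LOC236604 were called higher in both primary and transformed MEFs, 3 genes where independent lists would share 0.0349 (Fisher's exact test, one-sided p = 4.83e-06). The test treats genes as independent, and both lists come from 1 fit with a shared spread, so its p measures no repeatability over cultures. The lower lists shared 1 gene, Smchd1. Of the genes called in transformed MEFs, 25 of the 44 higher and 32 of the 103 lower ones had the same sign in primary MEFs. Across all genes, which are not independent replicates, Pearson's r between the primary and transformed differences was 0.003.

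Between the wildtype stages, transformation and chip changed together and cannot be told apart. Transformed MEFs had Cdkn2a, which encodes p16 and p19Arf, at least 266-fold higher than primary MEFs, and the proliferin genes Prl2c3 and Prl2c2 at least 176-fold and 162-fold. For 3 probes that have a number and no gene symbol as their name in the file the bound was 424-fold to 458-fold. Of 28 measured genes of the Ras and MAPK output 24 rose and none fell, among them Mmp3 (7.15 ± 0.28), Hmga1 (2.87 ± 0.13), Ccnd1 (2.08 ± 0.12) and Areg (5.12 ± 0.34), with camera adjusted p = 7.42e-14 and adjusted p = 0.001 with an estimated correlation. Interferon response genes rose in 23 of 26 (camera adjusted p = 5.43e-11, adjusted p = 0.107 with an estimated correlation and 2.77e-06 with fry). Lyz1 was at least 242-fold lower, Laptm5 at least 134-fold, Ttr at least 115-fold and Krt14 at least 101-fold. Of 17 macrophage markers 14 fell (camera adjusted p = 1.03e-13, adjusted p = 0.0779 with an estimated correlation and 9.26e-10 with fry). In all, 4558 genes were called, 2164 higher and 2394 lower. With the values as deposited the split was 1490 higher and 2773 lower.

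Wildtype tumours had the haemoglobin genes Hba-a1 at least 315-fold and Hbb-b1 at least 264-fold higher than wildtype transformed MEFs, and Cd74, the invariant chain of antigen presentation, at least 172-fold. All 17 macrophage markers rose, such as Laptm5 at least 227-fold and C1qb at least 33.4-fold (camera adjusted p = 7.05e-16, adjusted p = 0.0743 with an estimated correlation and 3.72e-10 with fry). Endothelial markers rose in 12 of 14 and fell in 1 (camera adjusted p = 4.44e-06, adjusted p = 0.267 with an estimated correlation and 2.96e-05 with fry). The growth factor gene Ptn (-5.96 ± 0.42), the matrix gene Mgp (-4.89 ± 0.59) and Gpc3 (-4.89 ± 0.38) fell. So did 21 of 26 interferon response genes, while 1 rose (camera adjusted p = 4.66e-10 for the interferon list, adjusted p = 0.12 with an estimated correlation and 2.44e-07 with fry). In all, 6437 genes were called, 3203 higher and 3234 lower. With the values as deposited the median of all genes was 0.37 instead of -0.02 and the split was 6433 higher and 1276 lower, so small shifts here depend on the scaling, and the SEs rest on the shared spread.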

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

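The tests of the epithelial markers, of the Lce genes, of Smchd1 and host markers in tumours, of Trp53 and of the spread of transformed replicates were chosen after the results were seen. The genotype difference differed between transformed and primary MEFs for 30 genes. The named ones are Klra4 (2.62), Elavl2 (1.55), Spin2c (1.51), Fosb (-2.46), Cyp2f2 (-2.25), Saa3 (-2.01), Gm4951 (-2.01), LOC100047583 (-1.99) and Ifit3 (-1.87), in log2 units. Of 100 splits of these replicates, 1 gave as many genes, the real one, and the highest other gave 26. For both differences between stages, the other splits were a random draw from all pairings of the splits of the 2 stages. A drawn pairing can keep the genotype split in 1 stage, so these splits do not stand for chance alone. Between tumours and transformed MEFs it differed for 8 genes in the shared fit, among them Rtl3 (1.88), Adh1 (1.61), Dnah1 (1.5), Gm4951 (1.38), Elmo3 (1.2), Gbp3 (1.12) and Cdc45 (-0.94), with Smchd1 as the remaining gene (0.95). Klra4 was not above background in primary MEFs, Rtl3 and Adh1 were not above it in tumours, and Gm4951 was below it in null transformed MEFs and wildtype tumours. Here 25 of 100 splits gave as many genes and the highest other gave 358, so chance is not excluded for this count.

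For the genotype counts, 3 against 3 gives 10 splits, too few for a share under 0.05. In primary MEFs 1 split, the real one, reached 15 genes and the highest other gave 2, and in transformed MEFs 1 split reached 147 and the highest other gave 1. In tumours 9 of the 10 splits reached 19 genes and the highest other gave 927, several times the real count. In tumours simulated with their own spread and no structure among recipients, the shared fit made 443 to 489 false calls in a run of 13870 genes. Of the 9 other splits 4 gave more than 489. Genes were drawn independently in the simulation, so this cannot tell a structure of the samples from correlation between genes. Neither was tested. For transformed against primary wildtype MEFs 1 split reached 4558 genes and for wildtype tumours against transformed MEFs 1 split reached 6437, with 0 as the highest other in both. Mixed splits put the large stage difference into the spread, so few or no calls could follow, and these stage counts do not test chance.

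All 15 keratinocyte and epithelial markers had a positive difference in null primary MEFs with none called, and the list passed camera with an estimated correlation in the shared fit (adjusted p = 0.0362) but not in the separate fit (adjusted p = 0.37, and 0.153 with fry). Release of the Lce cluster by loss of Smchd1 in every stage would place these genes higher in null transformed MEFs. The median difference of 14 Lce genes there was -0.01, and the 6 above background in either genotype had a median of -0.3. These 6 argue against release in transformed MEFs. The rest were not above background in either genotype, so they showed no release to a detectable level. In tumours the differences of the 14 genes lay between -0.14 and 0.21, with replicate means of 6.21 to 6.34, near background. More epithelial RNA in the null cultures is a candidate explanation that cannot be told apart from chance differences between cultures: the list median was 0.73, but the test over replicates had an adjusted p of 0.0877 (fry in limma). The marker means of the wildtype replicates spanned 8.55 to 9.34, so the share of such cells may also vary between cultures irrespective of genotype, and an effect of the genotype on epithelial cells stays untested.

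Smchd1 was higher in null tumours than in null transformed MEFs by 0.84 ± 0.12. A shift of the tumour chips or of the normalization cannot be told apart from other causes: wildtype Smchd1 moved by -0.11 ± 0.12 at this probe, but by 0.65 ± 0.12 at the second detected one, whose wildtype means were above background in both stages. RNA of wildtype cells of the recipient mouse remains a candidate explanation: in null tumours 17 of 17 macrophage markers were higher than in null transformed MEFs, with a median of 3.52 (3.37 with group means held at background), and 13 of 14 endothelial markers with a median of 1.89 (1.75).

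Interferon response genes were lower in null transformed MEFs. A different strength of the p53 knockdown cannot be told apart from other causes: Trp53 differed by -0.03 ± 0.18 between the genotypes, but 20 of 25 p53 target genes had a negative difference with none called. Their median was -0.14 (camera adjusted p = 0.0136, adjusted p = 0.297 with an estimated correlation; in the separate fit 0.0235, 0.37 and, with fry, 0.0363). Whether the 3 replicates stand for separate transformed cultures cannot be told apart from a single culture per genotype, because the labels do not say, and the median SD of genes between them was 0.129 against 0.14 in primary MEFs. With a single culture per genotype, a difference between 2 transformed cultures could look the same as an effect of Smchd1, which stays open.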

How the results depend on the processing

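The fits with one weight per stage and of the 4 culture groups, and the omission of one tumour array, were chosen after seeing the data; the causes were not tested. Smchd1 was lower in null samples under all settings in each stage, though in tumours it was not called by the separate fit or with one weight per stage. The separate fit per stage called 7 genes in primary MEFs, 906 in transformed MEFs and 0 in tumours (313 at an unadjusted p under 0.05, fewer than chance gives). Array quality weights gave 45, 1372 and 6, with 398 and 3 for the differences between transformed and primary MEFs and between tumours and transformed MEFs, and 7546 for transformed against primary wildtype MEFs. One weight per stage gave 44, 1318, 4, 361, 0 and 7246 in the same order, and the 4 culture groups gave 35, 1096, 327 and 7212 without tumours. With all 30 arrays and the recipient as a random block the counts were 29, 63, 82, 21, 17, 2753 and 4709, the last for wildtype tumours against transformed MEFs. With the replicate number as a random block in tumours they were 31, 73, 905, 27, 39, 2779 and 5541. With a replicate block in each stage they were 33, 45, 17, 24, 16, 2348 and 3792. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered wildtype and null replicates correlated at -0.37 to -0.01 in primary and 0.05 to 0.07 in transformed MEFs. These low values show no pairing but cannot exclude it. Tumour replicates as means of arrays sharing a number gave 29, 633, 1053, 214, 832, 6312 and 7953. Tumour chips alone gave 147, 694 and 1164. The values as deposited gave 12 genes whose genotype difference differed between tumours and transformed MEFs, and testing every kept probe gave 49 and 25 for the differences between stages.

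Leaving out each replicate gave 9 to 39 genes in primary MEFs (39 without wildtype replicate 2, 9 without null replicate 3), 45 to 227 in transformed MEFs, 16 to 690 in tumours (690 without wildtype recipient 3), 11 to 58 and 1 to 239 for the differences between stages, 3557 to 5353 and 5397 to 7363 for the wildtype stages, and 24 to 35 list tests. List tests called were 5 with an estimated correlation, 5 with fry and 23 without a probe filter, against 35. Over the omissions the tumour median of X-linked genes ran from -0.16 to 0.03 (without wildtype recipient 1), that of hypoxia genes from -0.05 (without wildtype recipient 3) to 0.38, and that of endothelial markers from -0.43 to 0.04 (without wildtype recipient 3), so these 3 changed sign. No background correction, normexp by detection p, median scaling and detection on every array of a group were not run, since the scanner columns belong to no sample here. Signal near background limits the low genes. Their folds between 2 groups are given as bounds, while the differences between stages for Klra4, Gm4951, Rtl3 and Adh1 are fitted values that include groups below background.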

Other observations

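Between 2164 rises and 2394 falls, wildtype transformed MEFs had 10 of 15 keratinocyte and epithelial markers called lower than in primary MEFs, none higher, and 13 lower adjusted over the list alone (camera adjusted p = 1.89e-05, adjusted p = 0.181 with an estimated correlation). Skeletal muscle markers were called lower in 14 of 17 (camera adjusted p = 1.77e-07, adjusted p = 0.255 with an estimated correlation). Fry gave the epithelial list an adjusted p of 7.72e-06 and the muscle list 3.46e-05. In a test for an array far from the others of its group, none of 28 groups of 9 tumour arrays over 14 genes had one. Over the analysed genes, however, the array of wildtype recipient 3 with replicate number 3 had a mean correlation of 0.894 to the other arrays of its group, where the other tumour arrays had 0.924 to 0.967. The 95th percentile of its background, 6.46 in log2 units, was the highest of the tumour arrays. Without this array, an omission chosen after seeing the data, the shared fit called 26 genes in tumours against 19 with it, and 690 without all arrays of that recipient.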
